A study of Mus musculus with 2 samples.

How the data were processed

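MicroRNA levels were measured on 1-colour arrays in 2 mouse epidermal keratinocyte lines, with 1 array for Pam212 and 1 for LY-1. Per the labels' protocols, both lines were grown to confluency in serum-containing medium without treatment, and total RNA was extracted with a small-RNA column kit and labelled with the dye Hy5 using the miRCURY LNA kit. Per the series text, 1 plate of each line was used, so the comparison has no biological replicate, and the arrays carried duplicate spots.

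The deposited table holds 1 intensity per probe and array on a linear scale. How the authors scanned the arrays, subtracted background, combined spots, scaled the intensities and chose the cells left as null is not given in the sources used here. The values are positive and not whole, and the medians over the 354 probes with a value on both arrays were 3.21 in Pam212 and 3.31 in LY-1. These differ by 0.05 on the log2 scale, less than the 0.1 set as the limit for using the deposited values as they are, so no further scaling was applied. No value per spot, no background value and no error per probe was used here, so the precision of a single intensity is unknown, and 1 array per line limits every comparison.

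Each of the 739 rows carries a miRBase mature-sequence accession in place of a name, and 5 rows carry several accessions. The files do not pair these accessions with miRNA names, and 0 of the 739 row identifiers occurred in the mouse gene table used for symbols. Names were not assigned from any other source. The miRNA families, genomic clusters and cell type marker lists fixed in advance, and miR-221 and miR-222 themselves, were therefore not analysed here by name, and probes are given by accession.

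The difference of a probe is log2 LY-1 intensity minus log2 Pam212 intensity, with no pseudocount, computed only where both arrays have a value. Counts and rankings used probes whose brighter value reached the median of all values of both arrays pooled, 2.26 intensity units. A probe was counted as higher or lower at a difference of at least 2-fold. This is a size threshold and not a test: with 1 array per line there is no spread between replicates, and no p-value or standard error was computed. The rule for named probes covered the 12 largest differences in each direction, the 5 brightest probes of each array, and the brightest probes with a value on 1 array only. Because accessions without names carry little meaning, 2 of the 12 in each direction are identified, those leading among probes bright on both arrays, a choice made after their values were seen. The brightest probe of both arrays and the brightest 1-array probe of each line are also identified, and the rest are summarised. The lists, the floor, the threshold and the alternatives were set before the data were examined, except for 2 alternatives added afterwards: leaving out rows with several accessions, and requiring both values at or above the pooled 75th percentile.

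Alternatives changed the scaling (median of the differences set to 0, one 75th percentile, quantile normalization, or a lowess trend with a span of 0.5 subtracted), the floor (none, the pooled 75th percentile of 11.0, or both values at the floor), the pseudocount (the 5th percentile, 1.02) and the size threshold (1.5-fold and 3-fold). Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and the figure used matplotlib 3.10.9. Scripts were tested on simulated data built from the Pam212 intensities of 351 probes, with 200 probes changed 4-fold and noise with an SD of 0.5 on the log2 scale. Over 100 simulated tables the 2-fold threshold recovered 97.8% of the changed probes and also took 4.67% of the unchanged ones. That noise was an assumed setting, the same at every brightness, since the error of these arrays is unknown. The simulation had no floor and no null cells. Both rates follow from these settings and do not give the accuracy of the calls in the real data.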

Results

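MicroRNAs are short non-coding RNAs that lower the output of messenger RNAs with matching sites. Their levels were profiled on arrays in Pam212, a mouse keratinocyte line of Balb/c origin that transformed spontaneously and does not metastasise, and in LY-1, a line derived from Pam212 that does. The comparison asks which miRNAs differ between a transformed keratinocyte line and its metastatic derivative. The series title puts miR-221 and miR-222, together with keratins 8 and 18, forward as possible markers of high-risk cutaneous squamous cell carcinoma. The data consist of 1 array per line, and there were no replicates of either line. The files identify probes by miRBase accession without miRNA names, so the values below are given by accession, and none is assigned by name to miR-221 or miR-222.

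Of the 739 probes, 460 had an intensity in Pam212 and 437 in LY-1, which is 62.2% and 59.1% of the array. A value was present on both arrays for 354 probes, in Pam212 only for 106, in LY-1 only for 83, and on neither for 196. Intensities ran from 0.943 to 51459 in Pam212 and from 0.948 to 51140 in LY-1. The median measured intensity was 2.16 in Pam212 and 2.44 in LY-1, and 40 probes in Pam212 and 48 in LY-1 reached 100 units.

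A few probes carried most of the signal in both lines. The brightest, MIMAT0011218, read 51459 in Pam212 and 51140 in LY-1, a log2 difference of -0.01, and accounted for 56.2% and 59.1% of the summed intensity. Whether this probe was near the upper limit of the scanner is unknown. The 5 brightest probes held 82.6% of the sum in Pam212 and 80.1% in LY-1, and 4 of these 5 were common to both arrays. The second brightest probe read 11555 in Pam212 and 9627 in LY-1. The probes ranked 3 and 4 lay between 3317 and 5468 on either array and differed by -0.72 and -0.57 on the log2 scale, both lower in LY-1.

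The 2 arrays gave similar ranks and intensities for the probes measured on both. Across the 354 probes measured on both arrays, Pearson's r of the log2 intensities was 0.964 and Spearman's rho was 0.872. These correlations are across probes, which are not independent replicates. They reflect the wide range of brightness among probes and leave out those with a value on 1 array only. No array of another sample was available to show what unlike samples would give. The median log2 difference, LY-1 minus Pam212, was 0.00. How the authors scaled the intensities is not given, so this median may have been set by the scaling.

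Among the 252 probes past the brightness floor, 32 were at least 2-fold higher in LY-1, 16 were at least 2-fold lower, and 204 differed by less. The split leant less to the higher side after quantile normalization, with 27 higher and 22 lower. Where both values had to reach the floor, 18 probes were higher and 6 lower. None of these differences has a replicate check, and no test of them was possible with 1 array per line.

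With no pseudocount, the largest difference was that of a probe that read 1.25 in Pam212 and 9.53 in LY-1, a log2 difference of 2.93. The next read 1.72 in Pam212 and 11.3 in LY-1, a log2 difference of 2.71. Both Pam212 values lay below the floor of 2.26, which only the brighter value of a probe had to reach. With a pseudocount of 1.02 the differences were 2.22 and 2.17. Both were then smaller than the 2.36 of a brighter probe, MIMAT0000669, so their lead depends on how low values are treated. The 12 probes that were highest in LY-1 relative to Pam212 had log2 differences from 1.76 to 2.93. Their LY-1 intensities ran from 3.20 to 349, and 9 of the 12 were under 20.

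In the other direction, the leading probe read 9.66 in Pam212 and 1.75 in LY-1, a log2 difference of -2.47. The next read 5.46 in Pam212 and 1.02 in LY-1, a log2 difference of -2.42, with the LY-1 value close to the lowest on that array, 0.948. With the pseudocount these differences were -1.95 and -1.66, so the size of both depends on how values near the bottom of the scale are treated. The 12 probes that were lowest in LY-1 relative to Pam212 had log2 differences from -2.47 to -1.15, and 9 of the 12 had a Pam212 intensity under 20.

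Among brighter probes, more were higher in LY-1 than lower in the values as deposited. Of 102 probes at or above 11.0 units on both arrays, 10 were at least 2-fold higher in LY-1 and 2 were at least 2-fold lower, a subset chosen after the data were seen. These counts were not repeated under the other scalings. Over the 252 probes past the floor, quantile normalization narrowed the split to 27 higher and 22 lower. The leading probe higher in LY-1 in this subset was MIMAT0000669, which read 67.3 in Pam212 and 349 in LY-1, a 5.19-fold difference. MIMAT0000670, with the next accession number, read 33.7 in Pam212 and 161 in LY-1, a 4.77-fold difference. The leading probes lower in LY-1 were MIMAT0000223, at 72.4 in Pam212 and 22.5 in LY-1 (3.21-fold), and MIMAT0009445, at 253 and 99.8 (2.54-fold). The files do not say which miRNAs these accessions stand for, and whether miR-221 or miR-222 is among the probes given here was not determined. Over the scalings and the pseudocount, their log2 differences ran from 2.25 to 2.38, from 1.88 to 2.26, from -1.87 to -1.64 and from -1.72 to -1.33.

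**Figure D1:**
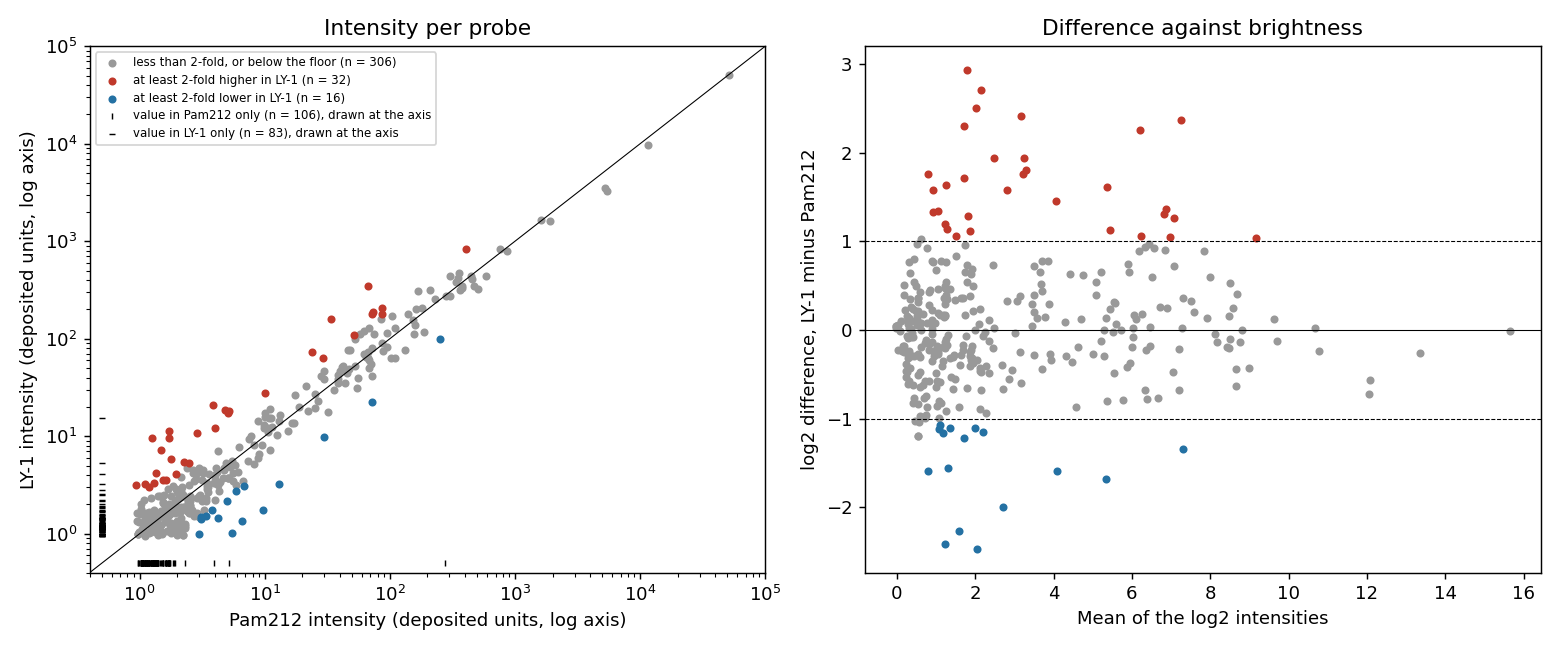
Left, intensity of each probe in Pam212 (x axis) and LY-1 (y axis), both in deposited units on log axes, with the line of equal intensity. Points are the 354 probes measured on both arrays, coloured for the 32 higher and 16 lower in LY-1, and ticks at the axes are the 106 and 83 probes with a value in 1 line only. Right, log2 difference (LY-1 minus Pam212) against the mean log2 intensity of the same 354 probes, with dashed lines at 2-fold; bright probes past the dashed lines lie mostly above zero.

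The spread of the differences did not shrink steadily with brightness. The SD of the log2 difference was 0.56 in the dimmest quartile of the 354 probes, 0.80 in the next, 0.94 in the one after and 0.69 in the brightest. The dimmest quartile had limited room for large differences, though 2 of its 89 probes were at least 2-fold higher in LY-1 and 5 were at least 2-fold lower. Its geometric means reached 1.74, the lowest values were 0.943 in Pam212 and 0.948 in LY-1, and probes lacking a value on either array were left out. Its low SD is therefore no sign that dim probes were measured more precisely. In the brightest quartile, 10 probes were at least 2-fold higher in LY-1 and 2 were at least 2-fold lower. These are the same probes as those counted above at or above 11.0 units on both arrays, so they are not a further result. Single arrays do not separate measurement error from differences between the lines in these values.

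Probes with a value in 1 line only were dim in that line. The 106 measured in Pam212 only had a median intensity of 1.27, and the 83 measured in LY-1 only had a median of 1.22. Past the floor were 4 of the former and 7 of the latter. MIMAT0000238 stood apart, with an intensity of 279 in Pam212, ranked 24 on that array, and no value in LY-1, whereas the next probe measured in Pam212 only read 5.16. In LY-1 the brightest of these probes was MIMAT0003409, at 15.5 with no value in Pam212, followed by one at 5.35. Neither has a measured fold, and the meaning of a null cell is not given in the sources used here.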

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

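The scaling alternatives (median set to 0, one 75th percentile, quantile normalization, lowess) gave 27 to 32 probes at least 2-fold higher in LY-1 and 16 to 22 lower, each within 1.5 times the main counts of 32 and 16. Stricter floors test fewer probes, so counts fall by construction: the pooled 75th percentile left 17 higher and 4 lower of 121 probes (14.0% and 3.31%, against 12.7% and 6.35% of 252), and both values at the floor left 18 and 6 of 186 (9.68% and 3.23%). With both values at the 75th percentile, an alternative added after seeing the data, the counts were 10 and 2 of 102 (9.80% and 1.96%), and leaving out rows with several accessions, also added then, gave 31 and 16. The pseudocount reduced the lower calls to 8, with 25 higher. The counts were 63 and 43 at a 1.5-fold threshold and 15 and 7 at a 3-fold threshold. At or above the pooled median, probes with a value on 1 array only numbered 4 in Pam212 and 7 in LY-1. The correlations past the floor were 0.954 (Pearson) and 0.870 (Spearman). For the 2 leading differences in each direction and the 4 identified bright probes, 12 of 40 values moved by over 0.1 on the log2 scale. The pseudocount moved the leading increase from 2.93 to 2.22 and one decrease from -2.42 to -1.66, each over 1.5 times as a fold. The former then no longer led, since MIMAT0000669 stood at 2.36. The direction of a difference cannot turn under a pseudocount. No value was run by name for miR-221, miR-222 or the fixed miRNA lists, because rows carry no names. Leaving out a replicate was not possible with 1 array per line.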

Other observations

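The patterns and all tests in this part were chosen after the data had been seen. They describe 2 arrays, and percentiles among reassigned or shuffled probes say nothing about the spread between cultures of either line.

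The differences varied with the accession number of the probe. miRBase gives numbers to sequences broadly in the order of registration. Among probes past the floor with 1 accession, the 103 numbered under 1000 had a median log2 difference of 0.29, and the 147 with later numbers had a median of -0.18, a gap of 0.48. The later numbers were not uniform: the 43 probes numbered 4000 to 4999 had a median of 0.29, as high as the earliest block, while the 36 numbered 3000 to 3999 had -0.20, the 19 numbered 5000 to 5999 had -0.40 and the 20 numbered 9000 to 9999 had -0.60. In the last of these blocks 3 of 20 probes had a positive log2 difference of any size, against 71 of 103 in the earliest. At the 2-fold threshold, 17 of the 103 earliest and 14 of the 147 later-numbered probes were higher in LY-1, and 7 and 9 were lower. The contrast in higher calls was smaller under other scalings. Higher calls numbered 14 and 16 after the lowess trend was subtracted, and 12 and 14 after quantile normalization.

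A trend with brightness does not account for the gap as a whole, since a gap of 0.37 remained after the lowess trend was subtracted. Dim probes do not account for it either, as the gap was 0.44 among the 102 probes at or above 11.0 units on both arrays. Reassigning the differences among probes of like brightness gave a smaller gap in 100% of 10000 draws, with a central 95% from -0.21 to 0.24. Whether the gap of 0.48 reflects a difference between the cell lines or a difference between 2 labelling reactions that favoured one kind of sequence cannot be told apart with 1 array per line. Probe sequences, which would be needed to compare the composition of the blocks, were not used here.

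One probe, MIMAT0000238, was bright in Pam212 (279) and had no value in LY-1. Of the Pam212 probes at or above 11.0 units, 1 (this probe) lacked a LY-1 value, and all others that bright had one. The probe may have been left out on the LY-1 array for a technical reason. Because the arrays carried duplicate spots, that reading needs either the loss of every spot of this probe or a combining step that dropped it. How the spots were combined is not given. If the null cell instead stands for a level below what the table reports, the decrease from Pam212 to the lowest LY-1 intensity would have to be at least 8.20 on the log2 scale, a bound that rests on that reading and not on a measured LY-1 value, against 2.47 for the greatest decrease among probes past the floor and measured on both arrays. Neither reading is excluded by the table, because it holds no spot flags and no second array.

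Probes with neighbouring accession numbers, which can be members of one family or cluster registered together, had like differences in a few cases. Over 100 neighbouring pairs past the floor, Pearson's r of the log2 differences was 0.27, above 98.9% of 10000 shuffles within blocks of 1000 numbers. Differences between whole blocks of 1000 numbers therefore do not by themselves account for this r, while narrower runs of numbers were not tested. The r was 0.24 after the lowess trend was subtracted. Both probes were at least 2-fold higher in LY-1 in 3 pairs, against a mean of 1.83 in the shuffles, 27.4% of which held 3 or more. MIMAT0000669 with MIMAT0000670 was such a pair. The remaining pairs shared a probe, so the 3 are not all separate cases. Leaving out such pairs lowers r by construction, so the shuffles were treated alike: r over the other 97 pairs was 0.04, above 74.9% of the shuffles, which gives no sign of likeness outside the 3 pairs. Among probes at or above 11.0 units on both arrays, r was 0.37 over 40 pairs, above 96.9% of shuffles but within their central 95%, from -0.23 to 0.38.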
